A study of Mus musculus with 10 samples.

How the data were processed

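Natural killer (NK) cells were sorted from the spleen and the bone marrow of BALB/c mice, and their messenger RNA was sequenced on an Illumina instrument, per the labels and the series design. In every sample the sort took cells with NKp46, CD122, CD27 and CD11b and without the lineage markers CD34, Ly6G, CD19 and CD3e, per the labels. These were divided by c-Kit in the spleen and by c-Kit and CD24 in the bone marrow. Complementary DNA was made and amplified with the SMARTer Ultra Low Input RNA Kit, and libraries were prepared with the TruSeq RNA Library Prep Kit, per the labels' protocols. The 10 libraries form 6 groups, 4 untreated groups of 2 libraries and 2 cultured groups of 1 library. The labels do not say whether replicates came from separate animals, so every p-value measures the spread between these samples.

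The deposited data are 2 tables of gene values, 1 for each tissue, with a column for each library. The authors deposited normalised values, which were read as FPKM (fragments by transcript length and mapped total). No header states the unit; it was taken from the values, which are not whole, are never negative and have column sums that fit neither counts nor TPM. The submitters' processing notes name Trimmomatic 0.32, HISAT2 2.0.5, Bowtie2 2.2.6 and StringTie 1.3.3b and the genome build mm10, without a role or an order. The annotation, the filters and the use of strand are not stated. The spleen table holds 43346 lines for 43280 gene symbols; for symbols on several lines, the line with the highest mean was kept and 66 lines were dropped. For 364 spleen genes an older symbol was matched to its current one. The bone marrow table holds 24532 symbols, of which 23407 are also in the spleen table. Of 72 ribosomal protein genes, Rps12 is listed at 0 in every spleen library, so a listing at 0 does not show that a transcript was absent. The bone marrow table has no mitochondrial, immunoglobulin or T cell receptor constant genes.

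The tables hold no read counts, so the sequencing depth is unknown. In the bone marrow table, steps worth 1 read were sought in FPKM below 2. The best match gave depths of 0.878 (c-Kit-CD24- replicate 2), 0.869 (c-Kit+CD24+ replicate 1), 0.902 (c-Kit+CD24+ replicate 2) and 0.904 (cultured) relative to c-Kit-CD24- replicate 1. It rests on ratios of up to 3 reads to 3 reads that matched within 0.002 on the log2 scale. In that order, 94 of 4021, 62 of 3579, 48 of 3256 and 38 of 2999 gene ratios matched. The median at the other depths tried was 26, 22, 19 and 15. Most values therefore showed no such step, and these depths are uncertain. The spleen values have 2 decimals, too few to read such steps. Values were tested as log2(FPKM + 1), so a fold change is on that scale and understates the change of low genes.

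Tests were run in R 4.3.3 with limma 3.58.1, with a mean trend and without robust fitting, on each table apart, over its 5 libraries in 3 groups. Genes with a mean of at least 1 FPKM over the 5 libraries of the table were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A cultured group has 1 library and therefore no replicate check. For these comparisons a gene was counted where its log2(FPKM + 1) in the cultured library lay at least 1 above, or at least 1 below, both untreated libraries. The filter includes the cultured library. A gene near 0 in all untreated libraries was therefore tested only where the cultured library was high, which favours upward counts and medians. The difference between the tissues' c-Kit effects was tested in 1 limma fit over the 8 untreated libraries, in which only differences within a table enter. The overlap of calls was set beside the product of the counts divided by the genes tested in both, with a one-sided Fisher's exact test across genes, which are not independent replicates.

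A total of 26 gene lists, fixed before the data were examined, cover sort markers, NK receptors, effectors, transcription factors and maturation stages, marker genes of other blood cells, cell cycle, metabolism, signalling, stress and homing. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists with at least 3 tested members. Camera with an estimated correlation and limma's fry were alternatives. With an estimated correlation camera uses the few residual degrees of freedom of the fit, so hardly any list could pass with so few libraries. For example, bone marrow terminal NK maturation genes had an estimated correlation of -0.044, below the preset one. Their unadjusted camera p still went from 1.3e-07 to 0.031. A list not past this setting is therefore not shown to be correlated or unchanged. For cultured libraries, a list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The same gene can be in several lists. Klra and Klrc receptor genes, haemoglobin genes, histone genes and Ifitm genes have near-identical copies and differ between mouse strains. The reference build is not of the BALB/c strain, so their single values are uncertain.

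The named genes follow a rule fixed before the data were examined. It takes all sort markers, and for each comparison and direction the 10 genes with the largest change that passed the test or size rule, did not overlap between groups and reached 5 FPKM in the higher group. It also takes up to 4 members of each list. Predicted genes count in totals and are not named. Coordinates are from GENCODE M21 on mm10, counted from 1.

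Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5, quantile normalisation, trimmed-mean scaling, no trend, fits on the 4 untreated libraries, a replicate block, and leaving out each library. For the cultured comparisons a size rule of 2 was an alternative. So was a limma contrast, which assumes that the lone cultured library varies like the other groups. A filter on the mean of the untreated libraries, and leaving out libraries in the comparisons between tissues, were added after the data were seen. The tests were run on simulated data with 200 changed genes. These were drawn only from genes with a mean of about 5 FPKM or more in the untreated libraries. All groups were given the same spread for a gene. The shares recovered therefore do not cover lower genes or groups of unequal spread. In the spleen simulation of 11025 genes, limma recovered 4.48% of genes changed by 1 on the log2 scale, 73.1% of those changed by 2 and 95.5% of those changed by 3. In the bone marrow simulation of 9987 genes these shares were 28.4%, 89.6% and 97.0%. Of 126 and 150 simulated calls, 11 and 7 were false. No sample was left out.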

Results

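The series holds 10 RNA-seq libraries of mouse NK cells, the cytotoxic lymphocytes marked by NKp46 and CD122. Its title names lineage reprogramming of c-Kit+CD24+ NK cells into myeloid cells, and the comparisons ask how c-Kit+ cells differ from c-Kit- cells and how they change in cytokine culture. From the spleen there were 2 c-Kit- and 2 c-Kit+ libraries, and 1 library of c-Kit+ cells treated with 20 ng/ml GM-CSF for 24 h. From the bone marrow there were 2 c-Kit-CD24- and 2 c-Kit+CD24+ libraries, and 1 library of c-Kit+CD24+ cells treated with 20 ng/ml IL-3, 20 ng/ml IL-6 and 50 ng/ml SCF for 24 h. Column sums were 680177 to 900779 FPKM in the spleen table and 426943 to 497005 FPKM in the bone marrow table. Replicates correlated across genes at r = 0.965 (spleen c-Kit-), 0.968 (spleen c-Kit+), 0.991 (bone marrow c-Kit-CD24-) and 0.969 (bone marrow c-Kit+CD24+). Group values below are mean FPKM ± SD over 2 libraries.

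The transcripts of the sort markers followed the labels for c-Kit. Kit, the receptor for stem cell factor (chromosome 5, 75574916 to 75656722), was at 0.565 ± 0.247 FPKM in spleen c-Kit- and 28.6 ± 8.20 FPKM in spleen c-Kit+ libraries (SD, n = 2). In the bone marrow it was at 0.508 ± 0.0313 FPKM in c-Kit-CD24- and 20.5 ± 9.50 FPKM in c-Kit+CD24+ libraries. Cd24a (chromosome 10, 43578284 to 43584265), which encodes CD24, was at 0.532 and 0.272 FPKM in the libraries labelled c-Kit+CD24+ and at 0.185 and 0.365 FPKM in those labelled c-Kit-CD24-, so its transcript did not separate these groups. In the spleen, where CD24 was not sorted, Cd24a was at 1.96 and 0.50 FPKM in c-Kit- and 7.13 and 13.3 FPKM in c-Kit+ libraries. Ncr1, which encodes NKp46 (chromosome 7, 4337724 to 4345164), was between 1771 FPKM (bone marrow c-Kit+CD24+ replicate 1) and 4005 FPKM (spleen c-Kit+ replicate 1) in the untreated libraries, and Cd19 was at or below 0.05 FPKM in all 10 libraries. The other excluded markers were not all as low. Spleen Cd34 was at 0.29 and 0.28 FPKM in c-Kit- and 5.25 and 5.58 FPKM in c-Kit+ libraries. Ly6g was at 5.71 and 2.24 FPKM in spleen c-Kit- and 0.11 and 0 FPKM in c-Kit+ libraries. Cd3e was at 0.18 to 2.21 FPKM in the untreated spleen libraries and 12.1 FPKM in the GM-CSF library. Bone marrow Cd3e was at 0.129 and 0.218 FPKM in c-Kit-CD24- and 0.611 and 1.19 FPKM in c-Kit+CD24+ libraries.

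**Figure D1:**
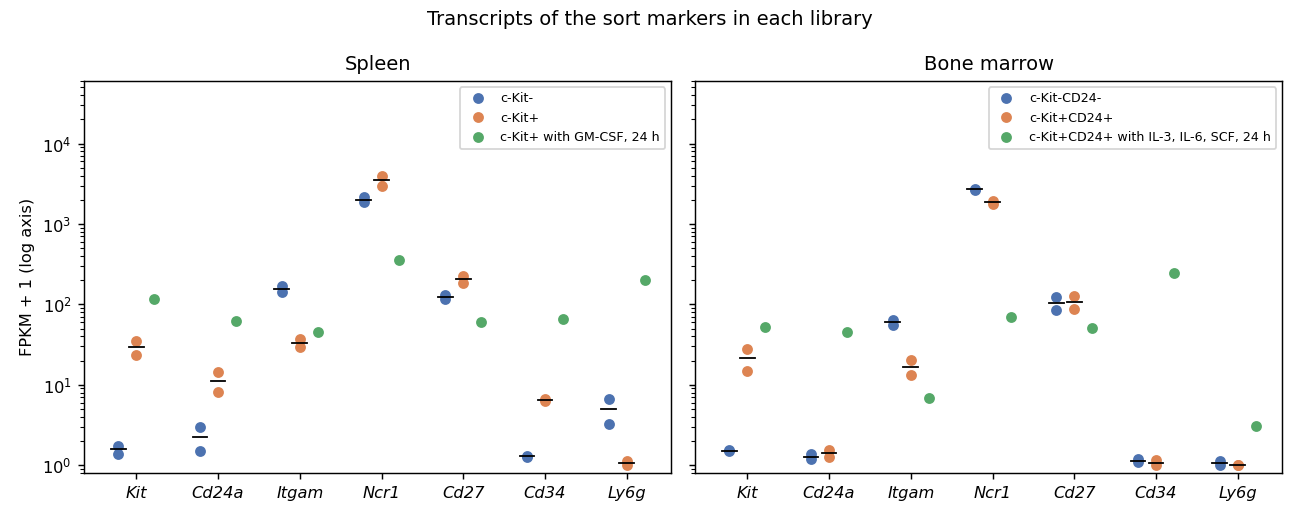
FPKM + 1 (log axis) of 7 sort marker genes in the spleen and bone marrow libraries; each point is 1 library and each bar the mean of 2 untreated libraries. Kit separates the c-Kit+ from the c-Kit- libraries in both tissues, and bone marrow Cd24a is below 1 FPKM in all 4 untreated libraries.

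Spleen c-Kit+ cells had more RNA of some red cell, platelet and mast cell genes than c-Kit- cells. They had less RNA of the late cytotoxic effector Gzmb and, as given below, of neutrophil genes as a list. Adult haemoglobin genes had the largest rises. Hba-a1 rose from 8.95 ± 0.523 to 272 ± 112 FPKM (log2 difference 4.71 ± 0.32 SE, limma adjusted p = 0.0286). Hbb-bt rose from 1.26 ± 0.693 to 109 ± 71.1 FPKM (5.48, adjusted p = 0.0428). Pf4, platelet factor 4 (chromosome 5, 90772435 to 90773383), rose from 0.270 ± 0.0141 to 23.9 ± 1.29 FPKM (4.29 ± 0.19 SE, adjusted p = 0.0134). The mast cell proteases Mcpt4 (0.07 and 0 against 21.5 and 9.03 FPKM) and Tpsb2 (listed at 0 in both c-Kit- libraries, 12.2 and 5.98 FPKM in c-Kit+) rose as well. The integrin gene Itgam (CD11b; chromosome 7, 128062640 to 128118491) fell from 153 ± 17.8 to 32.4 ± 5.83 FPKM, although CD11b was part of the gate in both groups. Gzmb, granzyme B, fell from 1069 ± 157 to 319 ± 19.5 FPKM (-1.73, adjusted p = 0.0473).

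Of 11783 spleen genes tested with limma, 57 were higher and 17 lower. The erythroid list had a median log2 difference of 1.97, with 4 of 11 tested members past the test and 11 higher when adjusted over the list alone (camera adjusted p = 3.58e-08). The mast cell, basophil and eosinophil list had a median of 1.63, with 2 of 14 members higher and 8 adjusted over the list alone (adjusted p = 0.00061). Its most abundant members, Prss34 (31.9 ± 18.1 against 243 ± 182 FPKM) and Mcpt8 (40.8 ± 19.3 against 235 ± 190 FPKM), did not pass. Of the haematopoietic progenitor list, Lmo2, a transcription cofactor of blood stem cells (0.415 ± 0.191 to 11.8 ± 1.87 FPKM), and Cd34 (0.285 ± 0.00707 to 5.42 ± 0.233 FPKM) rose. The list's median was 0.56 (adjusted p = 6.1e-05), and 6 of 17 members were higher adjusted over the list alone. It was 1.18 with a minimum mean of 5 FPKM, and 1.73 and 0.17 with pseudocounts of 0.1 and 5. MHC class II genes, which present antigen, had a median of 1.19 (adjusted p = 0.000141), or 2.12 with a minimum mean of 5 FPKM. H2-Eb1 rose from 1.02 ± 0.177 to 15.4 ± 6.17 FPKM, and 5 of 8 members were higher adjusted over the list alone. With an estimated correlation each of these 4 lists had an adjusted p = 0.633. Without c-Kit+ replicate 2, the erythroid median was 3.23 and the mast cell list median 2.54.

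Genes of NK cells moved in both directions. Gzmm, granzyme M, rose from 3.04 ± 0.933 to 52.1 ± 8.10 FPKM (3.73, limma adjusted p = 0.0334), and Cxcr6, a chemokine receptor of tissue-resident lymphocytes, rose from 0.985 ± 0.332 to 11.01 ± 0.0141 FPKM. The terminal NK maturation list had a median of -0.70 (adjusted p = 0.000958), with 2 of 12 members lower (Itgam and Gzmb) and 5 adjusted over the list alone. The NK receptor list had a median of 0.76 with 0 of 20 members past limma's test (8 higher adjusted over the list alone; camera adjusted p = 0.000162). Klrc1, which encodes the inhibitory receptor NKG2A, was at 426 ± 52.3 FPKM in c-Kit- and 1115 ± 93.2 FPKM in c-Kit+ libraries. The immature NK and ILC1 list had a median of 0.72 with 1 of 15 members higher, Cxcr6, and 8 higher and 1 lower adjusted over the list alone (adjusted p = 0.0242). NK transcription factors had a median of -0.49 with 0 of 12 past the test, and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.0116). With an estimated correlation these 4 lists had an adjusted p = 0.633. Without c-Kit- replicate 2 the immature NK and ILC1 list had an adjusted p = 0.0768 and the terminal maturation median was -0.44. Without c-Kit+ replicate 1 the NK receptor median was 0.49, and without c-Kit+ replicate 2 the transcription factor median was -0.79. With quantile normalisation the NK receptor median was 0.35, and the immature NK and ILC1 median 0.42 with an adjusted p = 0.0864.

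The neutrophil and granule list was lower (median -1.43, camera adjusted p = 0.00907; adjusted p = 0.639 with an estimated correlation). The members past limma's test were Ltf, lactoferrin (17.7 and 8.94 against 0.31 and 0.24 FPKM), and Retnlg (11.7 ± 4.10 to 0.515 ± 0.346 FPKM), 2 of 20, with 11 lower and 3 higher adjusted over the list alone. Immediate early and stress genes, which respond to handling and activation, had a median of -1.49 with 0 of 15 past limma's test (6 lower adjusted over the list alone, adjusted p = 6.1e-05). Dusp1 was at 1335 ± 631 FPKM in c-Kit- and 221 ± 214 FPKM in c-Kit+ libraries. Mitochondrial transcripts had a median of 1.62 with 0 of 9 past the test and 9 adjusted over the list alone (adjusted p = 5.3e-05). They took 1.45% and 1.34% of the FPKM sum in c-Kit- but 3.10% and 4.78% in c-Kit+ libraries. B cell (median 0.93, adjusted p = 0.0117), monocyte and macrophage (0.55, adjusted p = 0.0233) and interferon stimulated genes (0.49, adjusted p = 0.0278) were higher as lists with 0 members past the test. Adjusted over the list alone, 3, 0 and 4 of their members were higher. With an estimated correlation the other 5 lists had an adjusted p = 0.633, or adjusted p = 0.639 for the monocyte list. Without c-Kit- replicate 2 the monocyte list (adjusted p = 0.139) and the interferon list (0.0768) were no longer past the threshold, and without c-Kit+ replicate 1 they had adjusted p = 0.284 (median 0.26) and 0.0620. Without c-Kit+ replicate 2 the neutrophil list had an adjusted p = 0.386 and the monocyte median was 0.86. With quantile normalisation the monocyte list had an adjusted p = 0.0864, and with a minimum mean of 5 FPKM the B cell (0.0552), monocyte (0.0887) and interferon lists (0.134) did not pass. Without a filter the B cell list did not pass either (median 0.28, adjusted p = 0.128). The immediate early median was -0.98 without c-Kit- replicate 1 and -0.89 without c-Kit+ replicate 1. The other 12 lists had camera adjusted p of at least 0.152 and medians from -0.18 (cytotoxic effectors and NK chemokines, whose mean was 0.00) to 0.73 (sort markers).

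The groups did not overlap for 67.4% of the spleen genes, where chance gives 33.3%, and 3811 genes had an unadjusted p under 0.05, so the count of calls sits at a steep threshold. Without c-Kit- replicate 1 limma called 2 genes higher and 24 lower, 7 of these 26 also called with all libraries, and without c-Kit- replicate 2, c-Kit+ replicate 1 or c-Kit+ replicate 2 it called 0 genes (2452, 1664 and 3813 at an unadjusted p under 0.05).

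**Figure D2:**
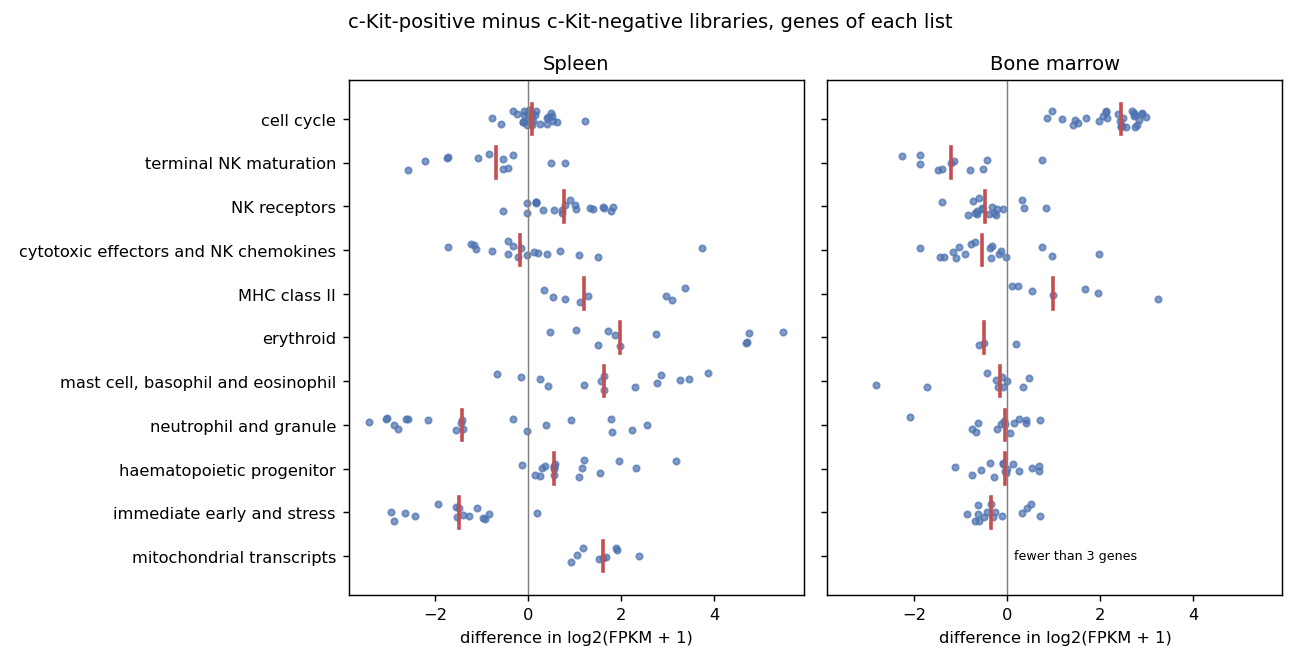
Difference in log2(FPKM + 1), c-Kit+ minus c-Kit-, of each tested gene (points) of 11 lists in spleen and bone marrow; red bars are list medians. The cell cycle median is 0.07 in spleen and 2.44 in bone marrow.

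Bone marrow c-Kit+CD24+ cells had far more RNA of the cell division machinery than c-Kit-CD24- cells. Aurkb, a mitotic kinase, rose from 15.2 ± 0.570 to 121 ± 7.95 FPKM (log2 difference 2.91 ± 0.15 SE, limma adjusted p = 0.0146). Plk1, another mitotic kinase, rose from 8.89 ± 0.774 to 69.2 ± 2.78 FPKM, and Ube2c, which marks mitotic proteins for degradation, from 17.9 ± 3.61 to 149 ± 28.9 FPKM. Of 29 tested cell cycle genes, 26 rose and 0 fell (29 higher adjusted over the list alone), with a median of 2.44 (camera adjusted p = 6.91e-33; adjusted p = 0.373 with an estimated correlation). The direction held under quantile normalisation (2.39) and trimmed-mean scaling (2.43). Also among the largest rises were Cdca8 (21.6 ± 3.56 to 165 ± 28.9 FPKM) and Birc5 (29.2 ± 3.84 to 229 ± 71.4 FPKM), both of the chromosomal passenger complex. The replication histones Hist1h2ag (12.9 ± 0.00201 to 114 ± 45.6 FPKM) and Hist1h2ap, and Ankle1 and Ube2v1, rose by similar amounts (log2 difference 2.88 for Ube2v1 to 2.99 for Hist1h2ag).

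Some genes of mature NK cells fell. Of the terminal NK maturation list, 5 of 11 members were lower and 0 higher, with 8 lower and 1 higher adjusted over the list alone. The list's median was -1.20 (camera adjusted p = 1.56e-06; adjusted p = 0.373 with an estimated correlation). Cma1, a chymase (93.2 ± 7.67 to 19.6 ± 8.82 FPKM), Gzmb (367 ± 45.9 to 102 ± 35.5 FPKM) and Itgam (58.6 ± 6.78 to 15.6 ± 4.96 FPKM) fell. So did S1pr5, a receptor for exit from tissue (96.6 ± 14.0 to 33.6 ± 0.688 FPKM), and Prdm1, a transcriptional repressor (32.2 ± 0.00243 to 13.5 ± 1.39 FPKM). NK receptors had a median of -0.47 with 0 of 18 past limma's test and 3 lower adjusted over the list alone (camera adjusted p = 0.000938; adjusted p = 0.562 with an estimated correlation). NK transcription factors had a median of -0.41 with 1 of 12 lower, Prdm1, and 2 lower and 1 higher adjusted over the list alone (adjusted p = 0.00315; adjusted p = 0.562 with an estimated correlation). Cytotoxic effectors and NK chemokines had a median of -0.53 (adjusted p = 0.00521; adjusted p = 0.594 with an estimated correlation). Of its 18 members Gzmb was lower and Gzmm higher (2.65 ± 0.257 to 13.6 ± 4.07 FPKM), with 7 lower and 2 higher adjusted over the list alone. Without c-Kit+CD24+ replicate 1 the effector list had a median of -0.32 (adjusted p = 0.235), and without replicate 2 a median of -0.82.

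Among MHC class II genes in the bone marrow, Cd74, the invariant chain (0.504 ± 0.0443 to 13.3 ± 0.155 FPKM), H2-Aa (0.141 ± 0.110 to 3.44 ± 0.797 FPKM) and H2-Eb1 (0.171 ± 0.0568 to 2.73 ± 0.00172 FPKM) rose. These were 3 of 7 members, or 4 adjusted over the list alone (median 0.99, limma camera adjusted p = 0.000211; adjusted p = 0.394 with an estimated correlation). Without c-Kit+CD24+ replicate 2 this median was 0.56, without a filter 0.38 and with a pseudocount of 5 it was 0.58. Myc and ribosome biogenesis genes (median 0.42, adjusted p = 0.000764) and glycolysis genes (0.42, adjusted p = 0.00521) were higher as lists with 0 of 16 and 0 of 13 members past the test. Adjusted over the list alone, 0 and 6 were higher, and both lists had an adjusted p = 0.394 with an estimated correlation. JAK-STAT targets had a median of -0.27 (adjusted p = 0.0458; adjusted p = 0.710 with an estimated correlation) with 0 of 11 past the test and 1 lower adjusted over the list alone. Without c-Kit-CD24- replicate 2 its median was -0.10 (adjusted p = 0.302), and without c-Kit+CD24+ replicate 1 it was -0.03 (adjusted p = 0.559). With trimmed-mean scaling it had an adjusted p = 0.0574, without a filter 0.110 and with a replicate block 0.0752. The erythroid (3 tested members), mast cell (10) and neutrophil (14) lists had medians of -0.51, -0.15 and -0.05. Leaving out 1 library moved these from -0.53 (c-Kit-CD24- replicate 1) to 0.27 (c-Kit-CD24- replicate 2), from -0.29 to 0 (the same libraries) and from -0.91 (c-Kit+CD24+ replicate 2) to 0.33 (c-Kit+CD24+ replicate 1). Mcpt8, of the mast cell list, fell from 3.86 ± 1.45 to 0.449 ± 0.0360 FPKM. The 15 lists not past the test had camera adjusted p of at least 0.141. Of these, the monocyte and macrophage list (median -0.24) and the sort markers (-0.06) had means of 0.21 and 0.20.

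Gstp2, a glutathione transferase, fell from 11.7 and 11.3 FPKM and was listed at 0 in both c-Kit+CD24+ libraries. Other large falls in the bone marrow were those of Cnbp, a nucleic acid binding protein (683 ± 51.7 to 172 ± 36.6 FPKM), Kcnj8, a potassium channel (8.23 ± 0.661 to 1.49 ± 0.0521 FPKM), Rhpn1, Cdc20b, Muc20 and Entpd1. In all, limma called 262 genes higher and 31 lower of 10504, with 1851 at an unadjusted p under 0.05, and groups that did not overlap for 52.6% of genes, where chance gives 33.3%. Without 1 library, 1 group has no replicate and the spread comes from the other pair alone. The pairs differed in spread. The SD of the log2 difference between replicates was 0.258 for c-Kit-CD24- and 0.512 for c-Kit+CD24+, with 93 and 406 genes at least 2-fold apart. Fewer genes were called without a c-Kit-CD24- library and more without a c-Kit+CD24+ library. Such counts therefore reflect which pair was left to set the spread, and the fit with all libraries pools these unequal spreads.

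The spleen and bone marrow c-Kit differences shared a small set of genes and differed in cell division, among other lists. In both tissues Kit, Gzmm, Cd300lf, Serpina3g, H2-Eb1, Ugt1a7c, Grtp1, Gpr34 and H2-Ea-ps rose. Crtam (an adhesion receptor of activated cytotoxic cells; 3.40 in spleen and 2.54 in bone marrow) and Spp1 (osteopontin; 2.49 and 2.78) rose as well, and Itgam, Gzmb and Serpinb9b (a granzyme inhibitor family member; -1.79 and -1.25) fell. These 11 higher and 3 lower genes compare with 1.01 and 0.0195 for independent lists (one-sided Fisher's exact test across genes, p = 2.59e-09 and 6.7e-07), and 0 genes were called in opposite directions where 0.288 would be by independent lists. Across 10062 genes, which are not independent replicates, the log2 differences correlated at Pearson's r = 0.321 and Spearman's rho = 0.355. Without c-Kit+CD24+ replicate 2 Pearson's r was 0.116, and without replicate 1 it was 0.432. The tissue, the table and the use of CD24 differ together between these comparisons.

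The c-Kit difference itself differed between the tissues for 346 genes, 192 of them with the higher value in bone marrow (limma interaction, adjusted p under the threshold). Of 29 cell cycle genes, 26 had a larger difference in bone marrow (median 2.32, camera adjusted p = 1.39e-28), for example Aurkb by 2.91 and Plk1 by 2.66. NK receptors (median -1.05, adjusted p = 3.87e-10; Klrc1 by -2.13 and Klrd1 by -1.70), the mast cell list (-1.75, adjusted p = 4.86e-06) and the progenitor list (-0.86, adjusted p = 3.91e-06; Lmo2 by -3.93) had lower differences in bone marrow than in spleen. Their medians were 0.76, 1.63 and 0.56 in spleen and -0.47, -0.15 and -0.04 in bone marrow. With an estimated correlation 0 of the 24 lists passed limma's camera (lowest adjusted p = 0.145, for the cell cycle list). The number of shared genes was 0 without any 1 of the 4 spleen libraries or of the 2 c-Kit-CD24- libraries, and 28 without c-Kit+CD24+ replicate 1. The number of genes that differed between tissues was 113 and 111 without spleen c-Kit- replicate 1 and 2, 131 without spleen c-Kit+ replicate 1, 120 and 110 without c-Kit-CD24- replicate 1 and 2, and 726 without c-Kit+CD24+ replicate 2.

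**Figure D3:**
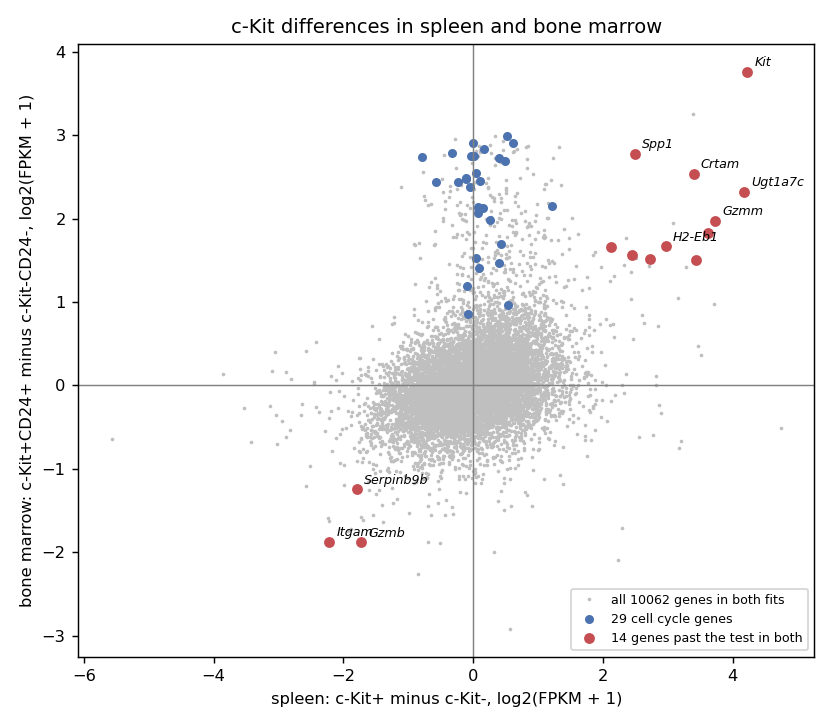
Difference in log2(FPKM + 1) between c-Kit+ and c-Kit- libraries in spleen (horizontal axis) and between c-Kit+CD24+ and c-Kit-CD24- libraries in bone marrow (vertical axis); each point is 1 of 10062 genes. The 14 genes past the test in both tissues are red, and the 29 cell cycle genes, blue, spread along the bone marrow axis around a spleen median of 0.07.

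Spleen c-Kit+ cells treated with GM-CSF for 24 h, a growth factor for granulocytes and macrophages, had much more RNA of neutrophil granule genes and much less RNA of NK receptors than untreated c-Kit+ cells. S100a8 and S100a9, which form calprotectin, were at 33.5 ± 30.6 and 30.1 ± 25.8 FPKM in the untreated libraries and at 6472 and 3823 FPKM in the treated one. Ngp was at 957.6 FPKM against 7.79 ± 7.25, Ltf (chromosome 9, 111019271 to 111042767) at 224 FPKM against 0.275 ± 0.0495, and Il6, an inflammatory cytokine, at 912 FPKM against 4.93 ± 1.94. Ly6g, a neutrophil surface marker excluded by the sort gate, was at 199.8 FPKM against 0.11 and 0 FPKM. In the other direction, the chemokine Ccl5 was at 155 FPKM against 11756 ± 224, the inhibitory receptor gene Klra3 at 25.4 against 1316 ± 232, Klrg1 at 1.45 against 121 ± 46.3, and Ncr1 at 355 against 3503 ± 711 FPKM.

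Of the 20 neutrophil and granule genes, 19 passed the size rule upward and 0 downward (median log2 change 5.70, percentile 100 among 10000 matched random lists). Myeloid cytokine receptors had a median of 3.20 with 10 of 11 upward, among them Csf2rb, the shared chain of the GM-CSF receptor (1.32 ± 0.460 to 93.0 FPKM), and Csf3r (0.735 ± 0.247 to 20.8 FPKM). Progenitor genes had a median of 2.09 with 14 of 17 upward, including Cd34 (5.42 ± 0.233 to 64.0 FPKM) and Adgrg1 (3.83 ± 1.24 to 176 FPKM). The mast cell, basophil and eosinophil list had a median of 2.49 with 9 of 14 upward and 1 downward (1.56 without c-Kit+ replicate 2), and MHC class II a median of 1.99 with 6 of 8 upward. Among myeloid transcription factors (median 1.42, 5 of 11 upward and 2 downward, or 3 and 3 with quantile normalisation), Spi1, which encodes PU.1, was at 47.7 FPKM against 3.26 ± 1.04. The monocyte and macrophage list was mixed (median 0.55, percentile 52.9, 6 upward and 3 downward of 13; median 2.19 without c-Kit+ replicate 1, 0.30 without c-Kit+ replicate 2 and -0.07 without c-Kit- replicate 1, and 0.16 and 0.26 with quantile normalisation and trimmed-mean scaling), with Lyz2, lysozyme, at 399 against 24.5 ± 12.2 FPKM. NK receptors had a median of -2.77 with 17 of 20 downward, cytotoxic effectors and NK chemokines -2.96 with 13 of 18 downward and 1 upward, and terminal maturation genes -1.48 with 8 of 12 downward. The erythroid list was mixed (median -1.54, 4 upward and 5 downward of 11; 0.58 without c-Kit+ replicate 2), with Hba-a1 at 15.7 against 272 ± 112 FPKM and Gata1 at 84.6 against 3.12 ± 0.601 FPKM. Mitochondrial transcripts had a median of -1.34 (-0.85 with quantile normalisation), at 1.59% of the FPKM sum.

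In all, 1703 genes passed the size rule upward and 562 downward (quantile normalisation 1057 and 970, trimmed-mean scaling 1225 and 805). The median of all 11783 genes was 0.30, and the scalings moved it by -0.36 and -0.28. Relative to it, the neutrophil list median was 5.39 and the NK receptor median -3.08. The directions of the lists named above held under each scaling. Without c-Kit+ replicate 2 the count was 3613. With 1 treated library there is no replicate check, and no cultured library without cytokine is labelled, so the cytokine and the culture change together in this contrast.

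**Figure D4:**
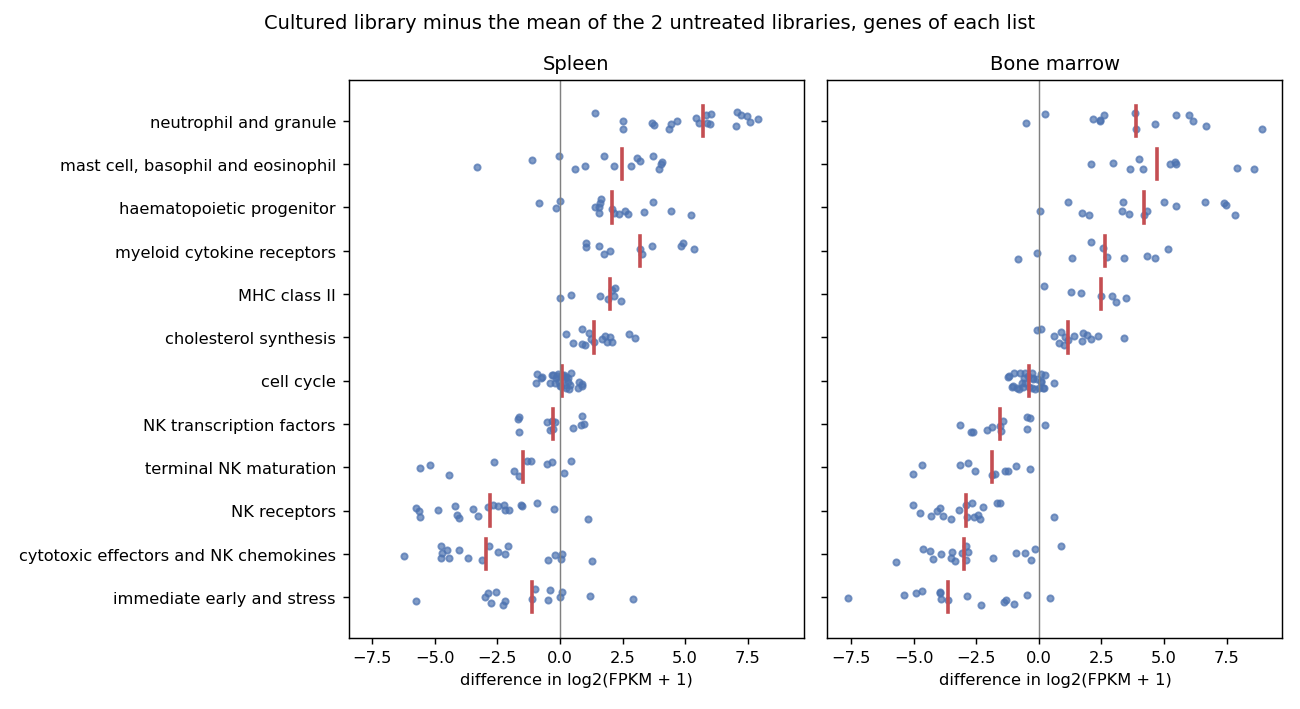
Difference in log2(FPKM + 1) between the 1 cultured library and the mean of 2 untreated libraries, for each gene (points) of 12 lists in spleen (GM-CSF) and bone marrow (IL-3, IL-6 and SCF); red bars are list medians. Neutrophil genes have medians of 5.70 and 3.86 and NK receptors of -2.77 and -2.90.

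Bone marrow c-Kit+CD24+ cells treated with IL-3, IL-6 and SCF for 24 h had much more RNA of several genes of granulocyte precursors, basophils and blood progenitors than untreated cells. Mpo, myeloperoxidase of granulocyte precursors (chromosome 11, 87793581 to 87804413), was at 721 FPKM against 0 and 1.27 FPKM, and Mcpt8, a basophil protease, at 552 against 0.449 ± 0.0360 FPKM. Cd34, a progenitor marker excluded by the gate, was at 242 FPKM against 0.143 and 0 FPKM. Pf4 (216 FPKM), Prss34 (239.8 FPKM), Ifitm1 (379 FPKM), Ctsg (101 FPKM) and Gata2 (43.2 FPKM) were listed at 0 in both untreated libraries. Fos, an immediate early gene, was at 2.72 against 747 ± 224 FPKM, Serpinb9b at 0.225 against 187 ± 6.29 FPKM, Ifng, interferon gamma, at 0.890 against 103 ± 46.7 FPKM, and Ncr1 at 68.6 against 1853 ± 117 FPKM.

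The mast cell, basophil and eosinophil list had a median log2 change of 4.72 with 10 of 10 upward, progenitor genes 4.22 with 14 of 15 upward, and neutrophil and granule genes 3.86 with 11 of 14 upward, each at percentile 100 of the matched random lists. Lmo2 was at 231 against 0.912 and 0 FPKM, and Elane, neutrophil elastase, at 160.2 against 2.03 ± 2.80 FPKM. Myeloid cytokine receptors had a median of 2.64 with 7 of 10 upward, including Flt3 (23.1 against 0 and 0.440 FPKM), and MHC class II 2.48 with 5 of 7 upward. Spi1 was at 84.3 against 0.311 ± 0.0213 FPKM, while the myeloid transcription factors as a list had a median of -0.40 with 2 upward and 3 downward of 9 (-0.07 without c-Kit+CD24+ replicate 2). NK receptors had a median of -2.90 with 17 of 18 downward, cytotoxic effectors -3.0 with 13 of 18 downward, NK transcription factors -1.54 with 8 of 12 downward, and immediate early genes -3.64 with 11 of 15 downward. Cell cycle genes had a median of -0.39 with 2 of 29 downward, Mki67 (27.3 ± 2.35 to 11.5 FPKM) and Rrm2 (296 ± 4.97 to 127 FPKM), at percentile 0.02 of the matched random lists. With quantile normalisation and trimmed-mean scaling 4 and 3 were downward, and without c-Kit+CD24+ replicate 2, 6.

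In all, 1137 genes passed the size rule upward and 639 downward (quantile normalisation 888 and 937, trimmed-mean scaling 937 and 766). The median of all 10504 genes was 0.17, and the scalings moved it by -0.23 and -0.17. Relative to it, the mast cell list median was 4.55 and the NK receptor median -3.07. The directions of the lists named held under each scaling. Without c-Kit+CD24+ replicate 2 the count was 2755 and, without replicate 1, the neutrophil list median was 2.16. As in the spleen, the cytokines and the culture change together, in 1 library.

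The changes in the 2 cultured libraries, which share no library, ran in the same direction for most genes past the size rule in both. Among 10062 genes, 695 were higher in both where independent lists give 131, 236 were lower in both where they give 23.8, and 7 went in opposite directions where they give 117. Csf2rb (5.35 in spleen and 5.16 in bone marrow), Spi1 (3.53 and 6.02), Adgrg1 (5.22 and 7.46) and the chemokine receptor gene Cxcr6 (5.36 and 3.56) were higher in both. Klra3 (-5.63 and -4.32), Klrg1 (-5.58 and -5.03), S1pr5 (-5.19 and -4.65) and Serpinb9b (-6.21 and -7.26) were lower in both. The log2 changes correlated across these genes at Pearson's r = 0.693 and Spearman's rho = 0.458. Genes are not independent replicates, and both media came with 24 h of culture. Both starting groups were NK cells, so genes near 0 in both could pass only upward. Independent lists leave this out, and some overlap would arise from the shared starting levels alone.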

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

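The tests of other dividing cells in the bone marrow and of dilution in the cultured libraries were chosen after the results were seen. The other tests below were written before those tests were run. Results are listed here because their c-Kit difference differed between spleen and bone marrow in limma's interaction test, which called 346 genes. Values are the bone marrow log2 difference minus the spleen one.

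By list, the medians were 2.32 for cell cycle and 1.18 for immediate early and stress genes. They were -2.33 for erythroid, -1.75 for mast cell, basophil and eosinophil, -1.05 for NK receptors, -0.91 for interferon stimulated, -0.86 for haematopoietic progenitor, -0.67 for sort markers, -0.58 for MHC class II, -0.52 for chemokine receptors and homing, and -0.34 for cytotoxic effector genes. These 11 of 24 lists passed at the preset correlation, and 0 passed limma's camera with an estimated correlation (lowest adjusted p = 0.145).

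Of the named genes, 10 had a larger difference in bone marrow, all of them up in c-Kit+CD24+ cells: Ankle1 (3.23), Aurkb (2.91), Cdca8 (2.77), Plk1 (2.66), Hist1h2ag (2.66), Ube2v1 (2.61), Hist1h2ap (2.47), Ube2c (2.47), Birc5 (2.29) and Mcm6 (1.29). The other 18 had a smaller or opposite difference in bone marrow. Among genes of platelets, red cells, mast cells and progenitors these were Pf4 (-6.84), Prss34 (-5.60), Hba-a2 (-5.25), Mcpt8 (-4.01), Lmo2 (-3.93), Cpa3 (-2.98), Cd34 (-2.41) and Gata1 (-2.33). Among genes of NK cells and homing they were Klrc1 (-2.13), S1pr5 (-1.97), Cxcr6 (-1.76), Gzmm (-1.75), Klrd1 (-1.70) and Klra3 (-1.65). The remaining 4 were Prss2 (-2.73), Cnbp (-2.31), Cd24a (-2.22) and Ugt1a7c (-1.85).

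The first pattern is the higher level of cell cycle genes in bone marrow c-Kit+CD24+ cells (median 2.44, lower quartile 1.98). Dividing blood progenitors or precursors of red cells, neutrophils or mast cells would bring their marker genes. Yet the highest median of these 4 lists was -0.0448, for progenitors (for neutrophil genes 0.33 without c-Kit+CD24+ replicate 1). The bound of 1 for these medians was set after the results were seen, so staying below it adds no support. That these markers did not rise as lists argues against such cells, with only 3 tested members for red cells. Transcript length bias would move genes of the same length and level, and 542 such genes had a median of -0.055, which argues against it. T cells, B cells and other antigen-presenting cells are not excluded: the MHC class II median was 0.994 (1.08 and 0.56 without c-Kit+CD24+ replicate 1 and 2) and the T cell median, over 3 genes, 0.66 (0.99 and 0.33), while dendritic cell genes had 0.29 (0.55 without c-Kit+CD24+ replicate 1), monocyte and macrophage genes -0.24, and Cd79b alone of the B cell list was tested (1.97 ± 0.252 and 2.04 ± 0.436 FPKM). Division of NK cells and RNA of such dividing cells therefore cannot be told apart, although the gate removes cells with CD3e or CD19.

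The second pattern is the higher level of red cell, mast cell and platelet genes in spleen c-Kit+ libraries. The gate's positive markers (NKp46, CD122, CD27 and CD11b) would remove red cells, mast cells and platelets that are not attached to NK cells. Further lists of their genes, written before the test, had medians of 0.54 (red cells, 8 of 14 genes tested, 5 higher in both c-Kit+ than in both c-Kit- libraries), 0.67 (mast cells and basophils, 6 of 13 tested, 4 higher) and 0.60 (platelets and megakaryocytes, 12 of 14 tested, 8 higher). Each lies between the 0.5 set as the bound against and the 1 set as the bound for RNA from such cells, so that RNA and transcription by the c-Kit+ cells themselves cannot be told apart. Members went both ways, as means of c-Kit- and c-Kit+ libraries. Rhag (0.06 to 2.19 FPKM), Tpsab1 (0 to 3.98 FPKM), Cyp11a1 (2.15 to 8.69 FPKM) and the platelet list gene Nrgn (119 to 268 FPKM) were higher. Bpgm (19.7 and 19.0 FPKM), Rab27b (46.5 and 31.6 FPKM) and the platelet list gene F2rl2 (11.7 and 6.885 FPKM) were not. Ppbp rose, but only from 0.03 to 0.545 FPKM, beside 23.9 FPKM of Pf4.

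The third pattern is the lower level of NK receptor genes in both cultured libraries. If unchanged NK cells were only diluted by other cells, their genes would fall by 1 factor, but the interquartile range of the changes was 2.22 over 20 genes in spleen and 1.57 over 18 genes in bone marrow, beside 0.273 and 0.431 between the untreated replicates. On log2(FPKM + 1), however, low genes would fall less than high ones under dilution as well, which the untreated replicates cannot show. The range therefore cannot decide on dilution alone, and a mixture of changed cells and other cells stays open. Whether 24 h of culture would do the same without a cytokine cannot be told apart from the cytokines, because 0 cultured libraries without a cytokine are labelled.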

How the results depend on the processing

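The filter on the untreated mean, and leaving out libraries in comparisons between tissues, were chosen after seeing the data. Depth could not be read for spleen and is uncertain for bone marrow. With 2 libraries a group, changes of 1 on the log2 scale were mostly missed in the simulation. The cause of each shift was not tested, except that fewer libraries or other tested genes change the adjustment. Within a tissue, leaving out 1 untreated library also leaves 1 pair alone to set the spread.

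The spleen comparison called 74 genes in the fit reported, 11 with pseudocount 5, 0 without a filter (4220 at an unadjusted p under 0.05 by limma), 751 with a minimum mean of 5, 34 with quantile normalisation, and 49 with trimmed-mean scaling. It called 608 with the filter on the untreated mean and 0 to 26 without 1 library. The bone marrow comparison called 293, 0 without a filter (2532 at an unadjusted p under 0.05) and 0 to 4297 without 1 library. Cultured spleen cells had 2265 genes past the size rule, 1335 with pseudocount 5, 1348 with a minimum mean of 5, 825 with a size rule of 2, and 2834 to 3613 without 1 library. Cultured bone marrow cells had 1776, then 1108, 1162, 664, and 2438 to 2755. A limma contrast called 1836 and 2219. Of the gene lists, 14 in spleen and 9 in bone marrow passed, and 6 and 4 with fry. With an estimated correlation 0 and 0 passed camera (1 and 2 at an unadjusted p under 0.05). That setting has few degrees of freedom, and lists with an estimated correlation below the preset one lost their calls too. In spleen 12 passed with quantile normalisation and 12 with a minimum mean of 5. The medians of lists of low genes moved with the pseudocount, as in spleen for erythroid (1.97, 4.17 with 0.1 and 1.00 with 5) and neutrophil genes (-1.43, -2.91 and -0.51). Genes called in both tissues numbered 14, then 4 with pseudocount 5, 44 with a minimum mean of 5, 0 without a filter, 7 with quantile normalisation and 0 to 28 without 1 library. The difference between tissues had 346 genes, and 110 to 726 without 1 library. The changes shared by both cultured libraries numbered 931, then 599 with pseudocount 5 and 542 with a minimum mean of 5.

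Replicates share the numbers 1 and 2, which are not shown to pair samples: same-numbered deviations correlated at -0.08 in spleen and 0.29 in bone marrow, over 2 pairs each. With a replicate block the counts were 318 (spleen), 983 (bone marrow) and 64 (both).

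Of the single genes named, 1 changed sign and passed the test with the other sign: bone marrow Ltb had a log2 difference of 0.06, 0.47 without c-Kit+CD24+ replicate 1 and -0.34 without replicate 2. Other named genes whose difference did not pass limma's test changed sign as well. Examples are bone marrow Ngp (0.41, and -1.80 and -2.07 without c-Kit-CD24- replicate 1 and c-Kit+CD24+ replicate 2) and spleen Lyz2 (0.26, and -0.33 and -0.25 without c-Kit- replicate 2 and c-Kit+ replicate 1).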

Other observations

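The values below come from lists and rules set before the data were examined. Sterol synthesis genes were higher as a group in both cultured libraries. The cholesterol synthesis list had a median log2 change of 1.38 with 9 of 15 genes upward by the size rule in spleen c-Kit+ cells with GM-CSF. It had a median of 1.15 with 8 of 15 upward in bone marrow c-Kit+CD24+ cells with IL-3, IL-6 and SCF, each at percentile 100 of matched random lists. With quantile normalisation the medians were 1.00 (6 upward) in spleen and 0.95 (7 upward) in bone marrow. With trimmed-mean scaling they were 1.08 (7 upward) and 0.98 (7 upward). Sqle, squalene epoxidase, went from 1.97 ± 0.410 to 22.7 FPKM in spleen and from 3.47 ± 0.359 to 45.6 FPKM in bone marrow. Ldlr, the LDL receptor, was at 9.44 FPKM against 0.570 ± 0.311 in spleen and at 6.91 FPKM against 0.756 and 0.332 in bone marrow. Myc and ribosome biogenesis genes had a median of 0.14 (2 upward and 1 downward of 16) with GM-CSF. This was 0.25 with quantile normalisation, -0.13 with trimmed-mean scaling, and 0.05 and 0.37 (3 and 4 upward) without c-Kit+ replicate 1 and 2. With IL-3, IL-6 and SCF it was 1.02 with 5 upward, 3 with trimmed-mean scaling and 10 without c-Kit+CD24+ replicate 1. There, Srm, spermidine synthase, went from 91.0 ± 27.6 to 342 FPKM and Npm1 from 304 ± 54.4 to 735 FPKM. That difference between media was not tested. Of glycolysis genes, 3 of 14 and 2 of 13 were upward (4 of 13 without c-Kit+CD24+ replicate 1), among them Aldoa (295 ± 10.5 to 965 FPKM in spleen, 225 ± 42.8 to 847 FPKM in bone marrow) and the lactate transporter Slc16a3.

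Cytokine signalling targets moved in both directions. Cish, induced by STAT5, went from 4.31 ± 0.127 to 60.7 FPKM with GM-CSF and from 1.75 ± 0.219 to 27.4 FPKM with IL-3, IL-6 and SCF. Id1 went from 1.75 ± 1.41 to 24.3 FPKM and from 0.862 ± 0.395 to 29.7 FPKM. Ccnd2 was at 22.2 FPKM against 85.2 ± 28.1 in spleen, and Socs3 at 10.9 against 90.0 ± 11.2 FPKM in bone marrow. Each JAK-STAT list had 4 genes upward and 1 downward (12 genes in spleen, 11 in bone marrow). In spleen it was 3 upward with 3 downward under quantile normalisation and 2 under trimmed-mean scaling, and 4 and 3 without c-Kit+ replicate 1. Among chemokine receptor and homing genes, 4 were upward and 5 downward of 12 in spleen, and 3 upward and 4 downward of 10 in bone marrow. Ccr7, a receptor for homing to lymph nodes, was at 43.5 against 6.74 ± 0.764 and 55.4 against 2.94 ± 0.618 FPKM, and Sell at 167 against 1236 ± 122 FPKM in bone marrow. Interferon stimulated genes had medians of -0.26 (1 upward and 3 downward of 13) and -1.03 (4 of 13 downward), with Zbp1 at 24.4 against 76.2 ± 13.1 FPKM and 5.54 against 34.2 ± 9.33 FPKM. Without spleen c-Kit+ replicate 1 and 2 the spleen interferon median was -0.13 and -0.49 (4 and 5 downward). It was -0.86 (0 upward and 6 downward) with quantile normalisation and -0.54 (0 and 4) with trimmed-mean scaling, and in bone marrow 7 were downward with quantile normalisation. The dendritic cell lists had 3 of 7 and 2 of 6 genes upward, with 1 downward in each, Itgax.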
